A study of Arabidopsis thaliana with 21 samples.

How the data were processed

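Roots of WS seedlings were compared across 7 fixation tubes from 1 C-9 flight, with 3 arrays per tube. Per the labels' protocols, seedlings were grown at 19 °C under 24 h light, roots were dissected from shoots after fixation, and 100 ng of total RNA per array was labelled for the Affymetrix AraGene 1.0 ST array. The deposited values are log2 expression values that the authors made with RMA (background correction, quantile normalization and summary per probe set); RMA, the R package oligo, limma, R 4.0.0 and TAIR10 are named in the submitters' processing notes. RMA forces the arrays to nearly the same distribution, so a shift of all transcripts at once cannot be seen. The table held 38408 probe sets for 21 arrays with no missing value, from 0.69 to 13.3, and the value columns of all 21 arrays were used.

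The platform annotation paired 17481 probe sets with at least 1 gene, 16722 with 1 gene and 759 with several, and left 20927 unnamed here. Of the 16722, 16574 matched a gene of RefSeq (assembly TAIR10.1) through the Entrez identifier, from which symbols were updated. No coordinates are given. A gene with several probe sets is represented by the one with the highest mean. Probe sets with several genes were tested and counted but not named. Of 315 loci in the gene lists, 43 were on named probe sets, so that many familiar touch, stress and cell type genes were not analysed here.

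All named probe sets were tested without a filter on brightness by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with the package data.table, version 1.17.8, in a single fit of 21 arrays with 7 group means and 14 residual degrees of freedom. Benjamini-Hochberg adjustment was made within each comparison and the threshold was an adjusted p of 0.05. Each tube was compared with level flight, tube A with tube B, and the later stages with each other, and a moderated F test covered all groups. Gene lists for touch, calcium signalling, reactive oxygen, cold, auxin, gravitropism, cell wall and plastid-encoded genes had at least 3 measured members and were tested with limma's camera at a preset correlation of 0.01. Of the calls of these lists, only the cell wall list at parabola 10 end against parabola 1 end held with an estimated correlation. The adjustment covered the 8 lists of a comparison, not the 11 comparisons, so this single call may be due to chance. The other alternative settings for lists were run only against level flight and did not test it. The other lists had fewer members and gave single genes only. Families of at least 8 genes sharing a symbol prefix were added after the annotation had been examined and before any gene's values were looked at.

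The design, the lists, the named-gene rule and all alternatives but those said to be added were fixed before the data were examined. In each comparison against level flight and in tube A against tube B, the text names the 8 largest rises and the 8 largest falls among single-gene probe sets past the threshold whose 3 arrays in one group lay all above or all below those of the other. It adds up to 4 passing members of each list with the smallest p, TCH1 to TCH4 at the last stage, and up to 10 genes passing with 1 sign in all 6 comparisons against level flight.

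Alternatives were a variance trend with robust estimation (for lists, the trend alone), probe sets above the median brightness, only the arrays compared, the replicate number as a block, array weights, the tube as a random block, cyclic loess, all probe sets named or not, and leaving out each array. The tube block with duplicateCorrelation gave a correlation of -0.073 between arrays of a tube, which cannot represent a variance between tubes. A correlation of 0.221 was therefore taken from the mean squares between tubes A and B and within tubes (ratio 1.85), after the data and the resulting counts had been seen. It rests on 1 pair of tubes and on a mean over probe sets. The fit takes it as known and equal for all probe sets, while every stage but the midpoint has a single tube. Probe sets that pass this fit are therefore not shown to exceed differences between tubes. The median ratio per probe set was 0.714. With 1 pair of tubes, the median of such a ratio lies below 1 even where tubes do not differ. A median under 1 therefore does not argue against a variance between tubes. Removal of trends on gene length and brightness (lowess span 0.3) was also added later.

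The fit was tested on simulated data for parabola 1 start against level flight, with 200 of 17481 probe sets changed in each of 10 runs. It called 37.9% of changes of 0.5, 97.5% of changes of 1 and 100% of changes of 1.5 on the log2 scale, and 4.51% of the calls were false. With simulated tube differences at a correlation of 0.22 and no stage effect, the fit called 28 to 80 probe sets for this comparison in 10 runs, and the tube block called 0. These runs gave all probe sets the same correlation and normally distributed deviations, which was not shown for the arrays. Tubes A and B, with no difference in stage, gave 245 calls. The range of 28 to 80 is therefore no upper bound on calls from tube differences.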

Results

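Gene expression was measured in whole roots of 12-day-old Arabidopsis thaliana seedlings of the Wassilewskija (WS) ecotype flown on a C-9 aircraft, which flies parabolas that alternate increased and near-zero gravity. Seedlings sat in Kennedy Space Center Fixation Tubes, hand-operated devices that flood the sample with the RNA preservative RNAlater. The 21 arrays formed 7 groups of 3. One group was fixed in level flight, 1 min before the first parabola. The others were fixed at the start of parabola 1, at the midpoint of parabola 1 in tube A, at the same midpoint in tube B, and at the ends of parabolas 1, 3 and 10. Per the labels, the replicates of a condition were root pools from a single tube. Tubes of the same stage could thus be compared only at the midpoint, where different crew members operated tubes A and B at one moment. No comparison between stages separated stage from tube, since level flight and every stage but the midpoint had a single tube. The p-values therefore measure the spread between root pools of a tube, not between tubes or flights. The number of arrays limits the precision, and column medians lay between 2.92 and 3.04 on the log2 scale.

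Over all 7 groups, the moderated F test of limma called 1383 of 17481 named probe sets. The first principal component, with 15.6% of the variance, placed parabola 1 start (mean score 14.1 ± 0.7, SD, n = 3) and midpoint tube A (17.7 ± 6.1) apart from level flight (-12.9 ± 1) and from midpoint tube B (-1.3 ± 6.4). The second, with 10.3%, placed parabola 1 end (13.3 ± 7) opposite parabola 10 end (-16.7 ± 5.5).

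**Figure D1:**
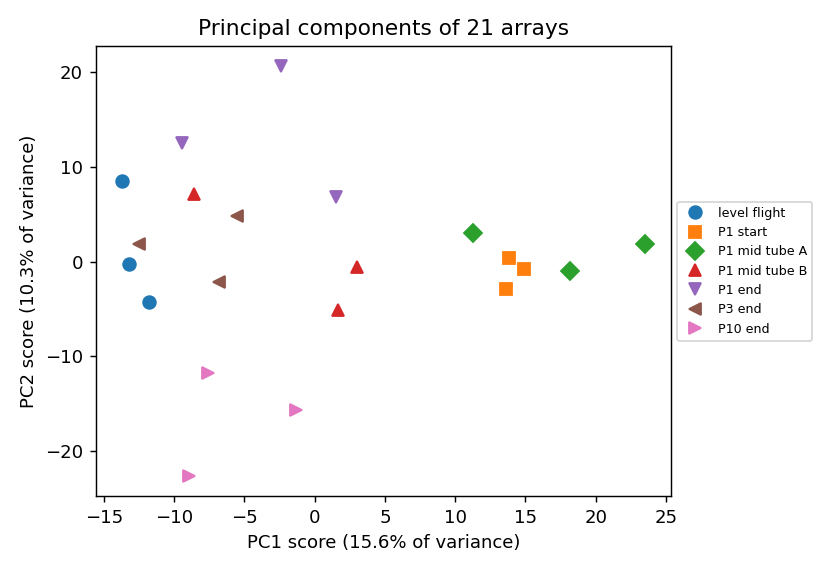
Scores of the 21 arrays on the first (15.6% of variance, horizontal) and second (10.3%, vertical) principal components of the log2 values, 3 arrays per tube. Parabola 1 start and midpoint tube A lie to the right, with mean scores of 14.1 and 17.7, while midpoint tube B has a mean of -1.3.

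The first comparison asked which transcripts differed between level flight and the very start of parabola 1. Here and below, fell and rose stand for differences between tubes, not for a change followed in the same roots. The largest changes were falls. GRX480, a glutaredoxin that binds TGA transcription factors, fell by 2.12 on the log2 scale (SE 0.33, 4.34-fold, limma adjusted p = 0.00054), from 6.71 ± 0.19 in level flight to 4.60 ± 0.11 (SD, n = 3 each). The C2H2 zinc finger gene AT3G53600 fell by 2.07, the AP2/ERF family gene AT1G22810 by 1.95, the acyltransferase family gene AT5G07860 by 1.94 and the AAA-type ATPase gene AT3G28510 by 1.77. AT4G37030 fell by 2.1, AT5G22140 by 1.99 and AT1G76600 by 1.83. The largest rises were smaller: the defensin gene PDF2.5 rose by 1.25 (SE 0.21, adjusted p = 0.0012), AT2G17080 by 1.25, PORB, which encodes a protochlorophyllide oxidoreductase, by 1.23, and AT3G07070 by 1.17. AT1G56020 and the lectin family gene AT2G25980 each rose by 1.14, the terpene synthase family gene AT1G33750 by 1.12 and the AP2/ERF family gene AT1G77640 by 1.11.

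Of the 5 measured members of the touch list, 4 fell at parabola 1 start and none rose. The calmodulin-like genes AT1G76640 (CML39), CML38 and CML37 changed by -1.64, -1.21 and -0.65, and the zinc finger gene STZ by -0.65. EXO had a value of 0.59 (adjusted p = 0.053). Adjusted over the list alone, 4 were lower and 1 higher. The list median was -0.65 (camera adjusted p = 2.25e-04), with adjusted p = 0.0934 with an estimated correlation. Of 4 calcium signalling genes, 2 fell, and 3 were lower adjusted over the list alone (adjusted p = 1.80e-04; adjusted p = 0.0934 with an estimated correlation). CML37 and CML38 stand in both lists. CML37 lay below the median of the arrays in both groups (2.92 ± 0.16 in level flight, 2.27 ± 0.08 at parabola 1 start), so its fall is read from a dim probe set. Single members of other lists fell: GH3.3, an auxin-conjugating enzyme (-1.18), GSTU25, a glutathione transferase (-1.18), AT1G72490 of the gravitropism list (-0.82) and AT4G33980 of the cold list (-0.45). As lists, auxin, cell wall, cold, gravitropism and reactive oxygen genes did not pass, with adjusted p from 0.12 to 0.528. Adjusted over the list alone, 1 auxin, 1 cell wall, 2 cold, 1 gravitropism and 1 reactive oxygen gene were lower. None of the 63 plastid-encoded genes passed singly, over all genes or adjusted over the list alone, but 61 had values above 0, with a median of 0.30 (camera adjusted p = 8.96e-09; adjusted p = 0.531 with an estimated correlation). The leaf transcripts RCA and LHCB4.1 were at 4.32 ± 0.15 and 3.93 ± 0.33 in level flight and at 4.62 ± 0.09 and 4.35 ± 0.11 at parabola 1 start (SD, n = 3 each; limma adjusted p = 0.303 and 0.32).

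In all, 728 probe sets passed limma's test at parabola 1 start, 246 higher and 482 lower, of which 16 and 113 changed at least 2-fold. With the tube as a random block, a fit chosen after seeing the data, 10 passed, 3 higher and 7 lower: AT2G25980, AT1G56020 and AT3G29410 were higher, and AT1G22810, AT4G37030, AT1G36640, AT5G52020, AT1G23710, AT3G04640 and UGT73B2 were lower. The count was 428, 442 and 464 without parabola 1 start replicates 2, 3 and 1, and 472, 491 and 442 without level flight replicates 1, 2 and 3.

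**Figure D2:**
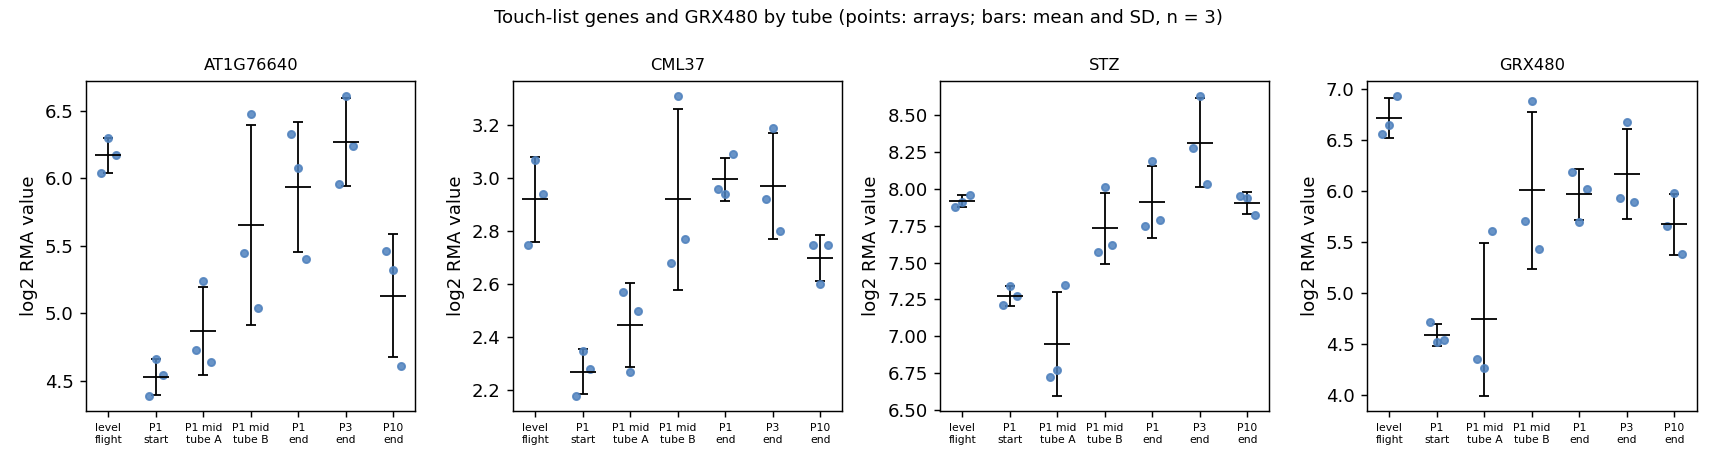
Log2 values of 3 touch-list genes (AT1G76640, CML37 and STZ) and of GRX480 in each tube, with 1 point per array and bars for mean and SD (n = 3). GRX480 had means of 6.71 in level flight, 4.60 at parabola 1 start, 4.74 in midpoint tube A and 6.01 in midpoint tube B.

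The midpoint of parabola 1, where increased gravity gave way to microgravity, was sampled by tubes A and B, and tube A was first compared with level flight. WRKY22, a transcription factor of pathogen-triggered signalling, fell by 2.08 (SE 0.19, adjusted p = 5.7e-06), from 5.54 ± 0.16 to 3.46 ± 0.41 (SD, n = 3 each). AT3G28510 fell by 2.21, AT4G37030 by 2.03, GRX480 by 1.97, AT3G53600 by 1.97, UGT73D1, a UDP-glycosyltransferase, by 1.91, the peroxidase family gene AT1G14550 by 1.73 and AT1G22810 by 1.73. The largest rises were AT3G45700 of the nitrate and peptide transporter family (1.38, SE 0.15), AT4G01390 (1.36), AT1G45015 (1.34), AT3G01260 (1.27), AT4G39675 (1.26), AT3G45160 (1.24), AT1G49500 (1.23) and PDF2.5 (1.2).

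Of the 5 touch-list genes, 3 fell in tube A: STZ (-0.97), CML38 (-1.08) and AT1G76640 (-1.3). Adjusted over the list alone, 4 were lower and 1 higher, and the list passed (camera adjusted p = 5.84e-04; adjusted p = 0.120 with an estimated correlation). CML38 and CML42 (-0.93) fell among the 4 calcium signalling genes, 3 adjusted over the list alone (adjusted p = 6.25e-04; adjusted p = 0.120 with an estimated correlation). LBD16, a lateral root regulator, changed by -0.62, the cell wall enzyme gene XTH18 by -0.82, AT1G72490 by -0.78 and GSTU25 by -1.21, each the 1 member of its list that was lower, also adjusted over the list alone. The 63 plastid-encoded genes had a median of 0.30, with no single call (adjusted p = 1.20e-09; adjusted p = 0.429 with an estimated correlation). The leaf transcripts LHCB4.1 and RCA, the 2 measured members of the list of 20 shoot markers, had values of 0.62 (adjusted p = 0.0828) and 0.18 (adjusted p = 0.611), and PORB, named here after its values were seen, rose by 1.19 (SE 0.25, adjusted p = 0.00535). In all, 898 probe sets passed, 289 higher and 609 lower. With only the 6 arrays compared, 445 passed, and without tube A replicate 2 the count was 548.

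In tube B, fixed at the same moment, 8 probe sets passed against the same level flight arrays. AT2G26690, the transporter gene NPF6.2, rose by 0.92 (SE 0.15, adjusted p = 0.035), AT1G61840 by 0.74 and the inositol phosphatase family gene AT1G71710 by 0.64. AT5G48430, of the aspartyl protease family, fell by 1.17, the peroxidase family gene AT1G49570 by 1.06, AT1G23710 by 0.99, AT1G36640 by 0.97 and AT2G32020 by 0.56. No gene of the lists of 3 or more members passed in tube B over all genes, and adjusted over the list alone 1 cell wall gene was lower; CML37 was at 2.92 in tube B and in level flight. The plastid-encoded list had a median of 0.11 (adjusted p = 0.00831; adjusted p = 0.814 with an estimated correlation). At an unadjusted p under 0.05, limma gave 1427 probe sets. The count moved to 5 with a variance trend, 3 with the replicate block and 1 with only the 6 arrays compared. It was 0 without level flight replicate 1 or 2 or tube B replicate 3, 2 without level flight replicate 3 and 17 without tube B replicate 2.

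Over both tubes, the mean of the 6 midpoint arrays differed from level flight at 450 probe sets, 123 higher and 327 lower. Of the touch list, 2 of 5 members fell, 3 adjusted over the list alone (median -0.58, adjusted p = 0.00212; adjusted p = 0.166 with an estimated correlation). Of the calcium signalling list, 2 of 4 fell, also adjusted over the list alone (adjusted p = 0.0112; adjusted p = 0.217 with an estimated correlation). Of the 6 cell wall genes, 1 fell, also adjusted over the list alone (adjusted p = 0.0302; adjusted p = 0.166 with an estimated correlation). Of the 63 plastid-encoded genes, none passed singly and 61 had values above 0, with a median of 0.21 (adjusted p = 8.64e-08; adjusted p = 0.513 with an estimated correlation). With the tube as a random block (chosen after seeing the data), no probe set passed limma's test for the midpoint mean, against 2343 at an unadjusted p under 0.05 without the block. The count was 252, 196 and 212 without level flight replicates 1, 2 and 3.

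Tubes A and B were then compared directly, which is also the test of whether their changes against level flight differed. Transcripts lower in tube A included AT2G43120, a pirin gene (-1.68, SE 0.23, adjusted p = 0.0018), which lay at 7.99 ± 0.43 in tube A and 9.66 ± 0.29 in tube B (SD, n = 3 each). AT3G28510 (-1.56), AT1G50590 (-1.55), WRKY22 (-1.32), AT1G17147 (-1.28), AT1G08050 (-1.2), JRG21, a jasmonate-regulated oxygenase (-1.19), and AT1G30700 (-1.17) were also lower. Higher in tube A were AT4G15990 (1.31), AT2G16019 (1.19), AT5G42200 (1.12), AT1G64370 (1.1), AT5G04080 (1.06), AT3G62160 (1.06), AT1G10800 (1.00) and AT5G26670 (0.90). STZ (-0.79) was the 1 touch-list gene that passed. Adjusted over the list alone, 4 touch genes were lower and 1 higher (median -0.60, camera adjusted p = 0.00339; adjusted p = 0.223 with an estimated correlation), and 3 of 4 calcium signalling genes were lower (adjusted p = 4.10e-04; adjusted p = 0.185 with an estimated correlation). The plastid-encoded list had a median of 0.19 (adjusted p = 1.24e-05; adjusted p = 0.872 with an estimated correlation).

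In all, 245 probe sets differed between tubes A and B, 51 higher and 194 lower in tube A. Among the 21 pairs of tubes this count ranked 10, above parabola 1 end (200) and parabola 3 end (80) against level flight. The count was 0 with only the 6 midpoint arrays in the fit (limma, 2149 at an unadjusted p under 0.05 with all arrays), 33 without tube B replicate 2, 74 without tube A replicate 2, 155 without tube A replicate 1 and 391 without tube A replicate 3.

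**Figure D3:**
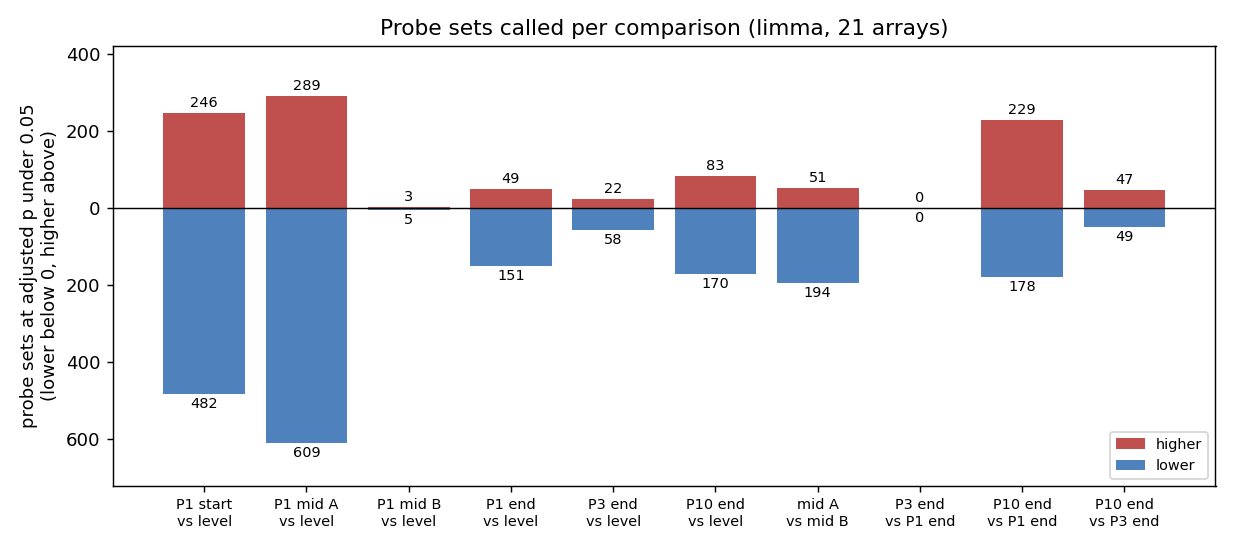
Number of probe sets past limma's adjusted p of 0.05 in each comparison, higher above 0 and lower below 0. Tube A gave 289 higher and 609 lower against level flight and tube B gave 3 and 5, while tube A against tube B gave 51 and 194.

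At the end of parabola 1, ASPGB1, an asparaginase gene, fell by 2.29 against level flight (SE 0.20, 4.90-fold, adjusted p = 1.2e-06), from 7.73 ± 0.17 to 5.44 ± 0.19 (SD, n = 3 each). AT5G48430 fell by 2.2. The GRAM domain genes AT5G23360, AT5G08350 and AT5G23350 fell by 1.78, 1.47 and 1.47, and AT1G21400, a subunit of the branched-chain keto acid dehydrogenase, by 1.57. AT2G44340 fell by 1.46 and AT1G56660 by 1.40. Rises were below 2-fold: AT3G28310 and AT5G45950 rose by 0.99, AT1G56020, PDF2.5 and AT1G62190 by 0.95, AT1G21326 by 0.91, AT5G47060 by 0.84 and AT5G38030 by 0.82. AT5G45950 lay below the array median in both groups (1.94 and 2.93) and was not shown to be above background. No gene of the touch, calcium signalling or other lists of 3 or more members passed over all genes. Adjusted over the list alone, 1 touch gene, 2 calcium signalling genes, 2 cold genes and 1 gravitropism gene were lower, and 1 auxin, 1 cell wall and 1 cold gene higher. The plastid-encoded genes shifted the other way from parabola 1 start, with 1 of 63 above 0 and a median of -0.24 (adjusted p = 8.42e-11; adjusted p = 0.642 with an estimated correlation). In all, 200 probe sets passed, 49 higher and 151 lower. With the tube as a random block (chosen after seeing the data), 6 passed, among them AT5G48430, ASPGB1, AT1G67480, AT1G52200 and AT3G29240, and with only the 6 arrays compared 76 passed. The count was 124, 111 and 69 without level flight replicates 1, 2 and 3, and 122 and 111 without parabola 1 end replicates 2 and 3.

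At the end of parabola 3, AT5G48430 fell by 2.06 (SE 0.18, 4.16-fold, adjusted p = 4.1e-06), from 6.24 ± 0.03 to 4.18 ± 0.33 (SD, n = 3 each). AT2G44340 fell by 1.51, the pectin methylesterase inhibitor family gene AT5G62360 by 1.37, UGT73D1 by 1.34, ASPGB1 by 1.2, AT1G53080 by 1.13, the chitinase family gene AT4G19720 by 1.1 and AT1G52200 by 1.09. The largest rises were AT1G21326 (1.33), AT1G33750 (1.02), AT3G20350 (0.98), AGL49 (0.92), AT5G48570, the heat-inducible FKBP gene ROF2 (0.91), AT2G29452 (0.91), AT5G42200 (0.90) and AT4G29780 (0.89). No member of a list of 3 or more passed over all genes; adjusted over the list alone, 1 auxin gene was higher and 1 calcium signalling gene lower. The plastid-encoded median was -0.08 (adjusted p = 0.0312; adjusted p = 0.699 with an estimated correlation). In all, 80 probe sets passed, 22 higher and 58 lower. With the tube as a random block (chosen after seeing the data) AT5G48430 alone passed. The count was 31, 28 and 36 without level flight replicates 1, 2 and 3, and 40 and 16 without parabola 3 end replicates 1 and 3.

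At the end of parabola 10, JRG21 rose by 1.28 against level flight (SE 0.18, adjusted p = 0.0011), from 3.94 ± 0.26 to 5.22 ± 0.15 (SD, n = 3 each). AT2G38823 rose by 1.31, AT2G31035 by 1.17, AT3G04855 by 1.1, AT3G54630 by 1.07, AT4G14930 and AT1G76470 by 1.03 and AT3G04000 by 1.00. GI, a circadian clock gene, rose by 0.90, AT3G10040 (HRA1), a regulator of the hypoxia response, by 0.88, the oxidative stress marker AT2G21640 by 0.78 and AKINBETA1, a subunit of the energy-sensing kinase SnRK1, by 0.66. AT3G10040 (1.83 in level flight, 2.71 ± 0.52 at parabola 10 end) and AT2G31035 (1.62 and 2.79 ± 0.59) lay below the array median in both groups and were not shown to be above background. The largest falls were AT5G62360 (-1.59), AT1G50590 (-1.58), AT1G36640 (-1.41), AT5G48430 (-1.40), AT4G19720 (-1.33), AT5G52670 (-1.32), AT5G41280 (-1.31) and AT3G61400 (-1.27).

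Of the 6 cell wall genes, the expansin gene EXPA4 (-0.89) and XTH18 (-0.79) fell at parabola 10 end, also adjusted over the list alone (median -0.43, adjusted p = 0.0103; adjusted p = 0.0694 with an estimated correlation). No calcium signalling gene passed over all genes and 1 was lower adjusted over the list alone (list adjusted p = 0.0346; adjusted p = 0.501 with an estimated correlation). The plastid-encoded median was 0.17 (adjusted p = 0.00233; adjusted p = 0.700 with an estimated correlation). The touch list did not pass (adjusted p = 0.396), with 1 gene higher and 1 lower adjusted over the list alone; in the same way 1 reactive oxygen gene was higher and 1 cold gene lower. TCH1 to TCH4, the touch genes named for this stage beforehand, had no named probe set and were not analysed here. In all, 253 probe sets passed, 83 higher and 170 lower. None passed with the tube as a random block (limma, chosen after seeing the data), against 2443 at an unadjusted p under 0.05 without it. The count was 95, 102 and 128 without level flight replicates 1, 2 and 3, and 124, 85 and 83 without parabola 10 end replicates 1, 2 and 3.

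AT5G48430 and AT1G36640 were lower in all 6 comparisons against level flight. AT5G48430 ranged from -0.87 at parabola 1 start to -2.2 at parabola 1 end, and AT1G36640 from -0.90 at parabola 1 end to -1.41 at parabola 10 end. This rests on their calls in tube B, which had no call without level flight replicate 1 or 2 or tube B replicate 3, and 1 lower call with the replicate block. In the 5 comparisons without tube B, 23 probe sets passed with 1 sign, 19 of them lower. In 50 simulations of unchanged groups against the shared level flight arrays the mean of both counts was 0. Unchanged groups yield almost no calls to share, so this 0 does not measure what a shared control adds. Parabola 1 start and tube A shared 77 higher and 348 lower probe sets. Independent lists of these sizes would share 4.07 and 16.8, values that leave out the shared level flight arrays. The simulations gave 0 shared calls, for the same reason as above. Across probe sets, which are not independent replicates, their fold changes correlated at r = 0.73 (0.50 simulated), with a covariance of 0.05 (0.0115 simulated, difference 0.0385). This was the highest r among the pairs of these comparisons. The lowest was 0.43, for parabola 1 end and parabola 10 end, and the smallest covariance difference was 0.00824, for tube B and parabola 3 end. The 3 level flight arrays were too few to be split, and a level flight tube that itself differs was not simulated. Part of the shared calls and of the correlation may therefore come from the shared control.

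The later stages were also compared with each other, without level flight. Parabola 3 end did not differ from parabola 1 end at any probe set in limma (1202 at an unadjusted p under 0.05), the duplicateCorrelation block gave 6, and without parabola 1 end replicate 1 limma gave 3. The plastid-encoded list was higher at parabola 3 end, with a median of 0.13 (adjusted p = 3.44e-06; adjusted p = 0.756 with an estimated correlation).

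Parabola 10 end was then compared with parabola 1 end, where the genes named were chosen after their values were seen, by the rule used for the other comparisons. AT1G21400 rose by 2.65 (SE 0.29, 6.27-fold, adjusted p = 2.8e-05), from 4.61 ± 0.46 to 7.25 ± 0.44 (SD, n = 3 each), PPDK, a pyruvate orthophosphate dikinase, by 2.42, ASPGB1 by 2.30 and SWEET2, a sugar transporter gene, by 1.71. AT5G56100 rose by 1.66, JRG21 by 1.63, AT4G36850 by 1.59 and AT5G08350 by 1.57. GH3.17, an auxin-conjugating enzyme, fell by 1.60, AT4G29930 by 1.59, GH9B8, a glycosyl hydrolase, by 1.42, AT1G49450 and AT4G01390 by 1.41, the pectate lyase family gene AT4G24780 by 1.35, EXPB3, an expansin, by 1.32 and AT5G38010 by 1.3. ASPGB1 was at 7.73 ± 0.17 in level flight and 7.74 ± 0.21 at parabola 10 end.

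The cell wall list was lower at parabola 10 end than at parabola 1 end, with 1 of 6 genes passing and 4 adjusted over the list alone (median -0.46, adjusted p = 0.00249; adjusted p = 0.0305 with an estimated correlation). The plastid-encoded list was higher, with 1 of 63 genes passing and none adjusted over the list alone (median 0.38, adjusted p = 8.06e-22; adjusted p = 0.263 with an estimated correlation). In all, 407 probe sets differed, 229 higher and 178 lower at parabola 10 end. With the tube as a random block (chosen after seeing the data), 33 passed, 27 higher and 6 lower, among them ASPGB1, AT1G21400, PPDK and SWEET2. Both stages have a single tube, so these 33 are not shown to exceed differences between tubes. The count in limma without the block was 157 without parabola 10 end replicate 2 and 209 without parabola 1 end replicate 3.

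Against parabola 3 end, 96 probe sets differed at parabola 10 end, 47 higher and 49 lower. The cell wall list was lower (median -0.25, no gene over all genes and 1 adjusted over the list alone, adjusted p = 0.0376; adjusted p = 0.202 with an estimated correlation), as was the touch list (median -0.27, also with 1 gene adjusted over the list alone, adjusted p = 0.0376; adjusted p = 0.269 with an estimated correlation). The plastid-encoded list was higher (median 0.27, adjusted p = 2.61e-11; adjusted p = 0.368 with an estimated correlation). With the tube as a random block, no probe set passed limma's test for parabola 10 end against parabola 3 end (1705 at an unadjusted p under 0.05 without it). The count was 43 without parabola 3 end replicate 3 and 48 and 39 without parabola 10 end replicates 1 and 3.

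**Figure D4:**
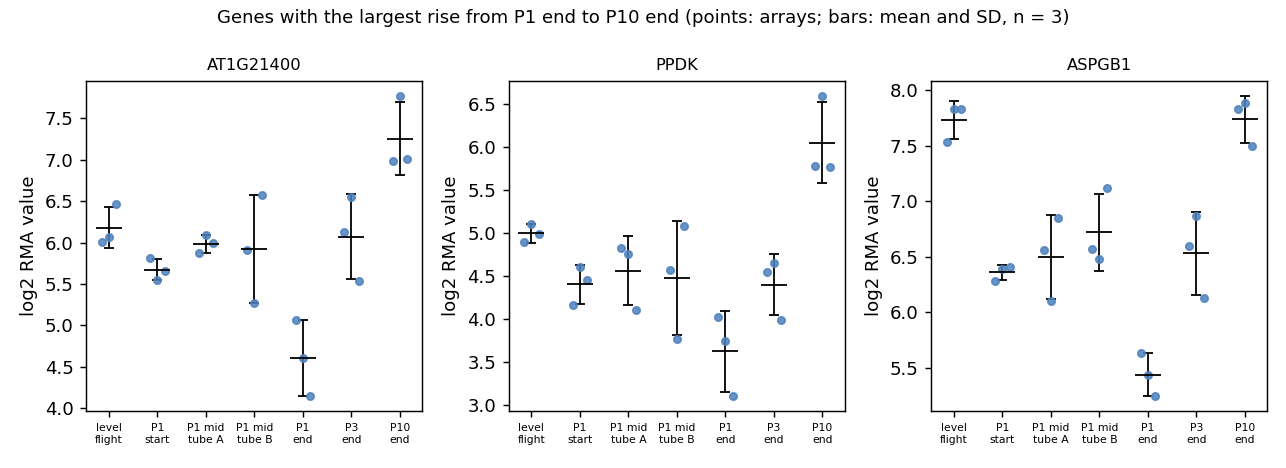
Log2 values of AT1G21400, PPDK and ASPGB1 in each tube, with 1 point per array and bars for mean and SD (n = 3). All 3 genes have their lowest mean at parabola 1 end, and AT1G21400 rises from a mean of 4.61 there to 7.25 at parabola 10 end.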

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

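The tests of tubes fixed at one moment and of shoot tissue were chosen after the result was seen; the tests of array trends, of gradual change, of single arrays and of other splits were chosen before their results were seen, the trend tests after the correlations with gene length had been seen. The bound set beforehand for the test of gradual change was dropped after its result was seen.

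The change against level flight differed between tubes A and B, fixed at one moment, at 245 probe sets, STZ and WRKY22 among them. A single array is a candidate cause: the count fell to 33 without tube B replicate 2, was 74 without tube A replicate 2 and 155 without tube A replicate 1, and rose to 391 without tube A replicate 3, so the size of the difference leans on single arrays. After removal of trends on gene length and brightness, 182 probe sets were called, 48 higher and 134 lower in tube A, and 177 of them were among the 245. Part of the calls may therefore depend on such a trend. No biological explanation was tested, since the labels give no difference in stage between these tubes. Different crew members operated them, so an effect of the operator cannot be told apart from one of the tube. Of the 84 splits of the 9 midpoint and level flight arrays, 2 gave as many calls as the midpoint group (206, fitted as 1 group), and the other, with 776, set the 3 arrays of tube A against tube B and level flight together, which points to a structure by tube.

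The 482 probe sets lower at parabola 1 start than in level flight, such as GRX480 and AT3G53600, had a median of -0.70 there. The median was -0.73 after removal of trends on gene length and brightness, which argues against such a trend as the whole cause. Shoot tissue in the root pools stays open. At parabola 1 start against level flight, LHCB4.1 had a value of 0.42 (SE 0.20, limma adjusted p = 0.32) and RCA of 0.30 (SE 0.14, adjusted p = 0.303). PORB rose by 1.23 and 61 of 63 plastid-encoded genes lay above 0. LHCB4.1, RCA and PORB had values of 0.62, 0.18 and 1.19 in tube A, of which PORB passed. In tube B, with a smaller median over the 482 probe sets, they had 0.38, 0.38 and 0.84, and none passed. At the ends of parabolas 1, 3 and 10, LHCB4.1 had 0.19, 0.39 and 0.55, RCA 0.12, 0.23 and 0.23 and PORB 0.82, 0.73 and 0.56, and none passed. LHCB4.1 and RCA thus did not follow the size of the falls, while PORB was highest at parabola 1 start and in tube A. A difference between tubes stays open and is consistent with the midpoint pair: over these probe sets, chosen without the midpoint arrays, tube A lay below tube B with a median of -0.40. Relative to level flight, the medians were -0.67 in tube A, -0.30 in tube B and -0.38, -0.30 and -0.32 at the ends of parabolas 1, 3 and 10. The level flight arrays also chose these probe sets and so may lower all of these values. A change of flight stage was not excluded, since each stage but the midpoint, level flight included, has a single tube. Level flight was fixed 1 min before the first parabola, so a stage response at parabola 1 start would have had to arise in a short time. Rates of transcript loss were not measured here.

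The change against level flight differed between parabola 10 end and parabola 1 end at 407 probe sets, ASPGB1 and PPDK among them. After removal of trends on length and brightness, 90.4% of the calls were left, which argues against such a trend. A gradual change over the parabolas stays open. On a scale from 0 at parabola 1 end to 1 at parabola 10 end, parabola 3 end had a median position of 0.36 ± 0.09 (SD over 3 arrays). An even change per parabola gives 0.222. Tubes fixed before parabola 1 end lay at 0.37 ± 0.02 (parabola 1 start), 0.38 ± 0.04 (tube A) and 0.47 ± 0.19 (tube B). The position of parabola 3 end therefore cannot decide on a gradual change. The bound set beforehand, the highest of the earlier tubes (level flight, 0.50 ± 0.09), was wrong. A tube unrelated to either end also falls mid-scale on probe sets chosen for the difference between the ends. From parabola 1 end over parabola 3 end to parabola 10 end, the means were 4.61, 6.07 and 7.25 for AT1G21400, 5.44, 6.53 and 7.74 for ASPGB1 and 3.62, 4.4 and 6.04 for PPDK, 3 genes chosen for their rise, while no probe set passed limma's test between parabola 1 end and parabola 3 end (1202 at an unadjusted p under 0.05, 6 with the duplicateCorrelation block). A change particular to the parabola 1 end tube or to the parabola 10 end tube stays open too.

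The change against level flight also differed between parabola 10 end and parabola 3 end, at 96 probe sets. Among the 20927 unnamed probe sets, which the comparisons did not use, limma called 495 at parabola 1 start, 646 in tube A, 135 at parabola 1 end, 35 at parabola 3 end and 78 at parabola 10 end against level flight.

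For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05 (the smallest is 0.1). The real split gave the highest count, alone (1 of 10), in 9 of these comparisons. The real counts and the highest of the other splits were 728 and 0 at parabola 1 start, 898 and 2 in tube A, 8 and 1 in tube B, 200 and 0 at parabola 1 end, 80 and 0 at parabola 3 end and 253 and 0 at parabola 10 end against level flight. They were 245 and 4 for tube A against tube B, 407 and 0 for parabola 10 end against parabola 1 end and 96 and 0 against parabola 3 end. For parabola 3 end against parabola 1 end the real count was 0 and the highest other 1, so that all 10 splits gave as many. For the F test, 1 of 100 groupings of the 21 arrays, the real one, gave as many as 1383 calls (highest other 15). For the midpoint mean, 2 of 84 splits gave as many as the real one. Both shares lie under 0.05, but they would measure chance only if the arrays were independent. These splits ignore that the arrays of a tube are not independent, so they do not exclude a difference between tubes: for the midpoint mean the split by tube A gave 776 against 206, and the fit with the tube as a random block called 0 (2343 at an unadjusted p under 0.05 in limma without it).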

How the results depend on the processing

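The 133 calls named by the rule, against level flight and between tubes A and B, had no change of sign in 2014 refits, and 410 of these lost the call. The 22 calls named after their values were seen, mostly for parabola 10 end against parabola 1 end, had none in 352 refits, and 24 lost the call. PORB in tube A, also named after its values were seen, was not among the 22. The unchanged signs are no support, since many refits leave the differences of group means as they are. For genes whose groups do not overlap, leaving out or reweighting an array cannot reverse the sign either. The block with the moment-based tube correlation, chosen after seeing the data, ended 74 of the 82 calls by the rule that it could test and 9 of the 22, so that 13 of these passed, all for parabola 10 end against parabola 1 end. It left 10 probe sets at parabola 1 start, 0 for the midpoint mean, 6 at parabola 1 end, 1 at parabola 3 end and 0 at parabola 10 end against level flight, 33 for parabola 10 end against parabola 1 end and 0 against parabola 3 end. Its construction shows why: it adds a variance between tubes. That variance comes from 1 pair of tubes and is taken as known, so the calls left are not shown to exceed differences between tubes. The duplicateCorrelation block, with a correlation below 0, gave 303 at parabola 1 end (116 higher, 187 lower), 159 at parabola 3 end (70 and 89), 421 at parabola 10 end (190 and 231), 6 for parabola 3 end against parabola 1 end, 619 for parabola 10 end against parabola 1 end and 205 against parabola 3 end.

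With only the arrays compared, and so fewer degrees of freedom, counts were 445 in tube A, 1 in tube B, 152 for the midpoint mean, 76 at parabola 1 end (9 higher, 67 lower), 0 for tube A against tube B, 156 for parabola 10 end against parabola 1 end and 45 against parabola 3 end. Among probe sets above the median brightness there were 308 at parabola 1 end, 152 at parabola 3 end, 438 at parabola 10 end and 162 for parabola 10 end against parabola 3 end. Array weights gave 199 at parabola 3 end, 491 at parabola 10 end and 254 for parabola 10 end against parabola 3 end. The variance trend gave 5 in tube B and 122 at parabola 3 end. All probe sets, named or not, gave 1181 at parabola 1 start, 1520 in tube A, 0 in tube B, 712 for parabola 10 end against parabola 1 end and 2129 in the F test. Cyclic loess gave gene counts within 1.5 times those reported and moved the split at parabola 10 end from 83 higher and 170 lower to 56 and 202. Beyond the settings whose construction is named, the cause was not tested.

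The number of lists called fell from 3 to 0 at parabola 1 start, in tube A and at parabola 10 end, from 4 to 0 for the midpoint mean and from 1 to 0 in tube B and at parabola 1 and parabola 3 end with an estimated correlation. Among bright probe sets it was 0 in tube B and 2 for the midpoint mean, and in tube B it was 2 with cyclic loess.

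Leaving out 1 array gave 428 to 491 at parabola 1 start, 548 to 944 in tube A, 0 to 17 in tube B, 196 to 553 for the midpoint mean, 69 to 172 at parabola 1 end, 16 to 68 at parabola 3 end and 83 to 128 at parabola 10 end against level flight. It gave 33 to 391 for tube A against tube B, 0 to 3 for parabola 3 end against parabola 1 end, 157 to 397 for parabola 10 end against parabola 1 end, 39 to 83 against parabola 3 end and 1020 to 1409 in the F test. The lowest counts came without parabola 1 start replicate 2 (428), tube A replicate 2 (548), level flight replicate 2 (196, midpoint mean), level flight replicate 3 (69), parabola 3 end replicate 3 (16), parabola 10 end replicate 3 (83 and 39), tube B replicate 2 (33) and parabola 10 end replicate 2 (157).

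The replicate numbers did not pair the arrays: same-numbered arrays of different tubes had a mean correlation of deviations of 0.008, 3 of 63 pairs were over 0.1, and 8 of 21 arrays correlated best with their own number. The replicate block gave 693 at parabola 1 start, 890 in tube A, 3 in tube B, 422 for the midpoint mean, 170 at parabola 1 end, 71 at parabola 3 end, 231 at parabola 10 end, 224 for tube A against tube B, 0, 396 and 81 between the later stages and 1361 in the F test, and 2 lists in tube B. Signal over background was not measured here; CML37, AT5G45950, AT2G31035 and AT3G10040, each in 1 comparison, were called with both group means below the array median.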

Other observations

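The test of the branched-chain amino acid breakdown genes was chosen after the result was seen, as were the counts of 1 tube against the mean of the others; the families were fixed after the annotation, but not the values, had been examined.

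Of 6 measured genes for the breakdown of branched-chain amino acids, from a list of 17, AT1G21400, MCCB, ETFQO and ALDH6B2 fell at parabola 1 end against level flight (-1.57, -0.88, -0.76 and -0.74), and the same 4 rose from parabola 1 end to parabola 10 end, by 2.65, 1.57, 1.31 and 1.16. AT2G26800 (0.15, adjusted p = 0.56) and ETFALPHA (0.00, adjusted p = 1) did not pass between these stages, and ETFALPHA was at -0.28 in tube B and -0.06 at parabola 1 end against level flight. The list was lower at parabola 1 end than in level flight (median -0.75, camera adjusted p = 1.3e-07; adjusted p = 0.037 with an estimated correlation). It was higher at parabola 3 end than at parabola 1 end (median 0.42, adjusted p = 1.7e-06; adjusted p = 0.049 with an estimated correlation) and at parabola 10 end than at parabola 3 end (median 0.81, adjusted p = 7.1e-09; adjusted p = 0.031 with an estimated correlation), adjusted over 11 comparisons. At parabola 10 end against level flight, its call (median 0.49, adjusted p = 1.2e-04) was lost, with adjusted p = 0.10 with an estimated correlation. The 4 genes prompted the list, so its count and its tests are not independent evidence. In the fit with the tube as a random block, all 4 passed between parabola 10 end and parabola 1 end, and none of the 4 passed between parabola 1 end and level flight. Passing that fit does not show that the 4 exceed differences between tubes.

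Of the 35 families, 6 passed between parabola 10 end and parabola 1 end, 5 of them also with an estimated correlation. Among these, the cell wall families EXPA and XTH were lower at parabola 10 end, and the others are not given. EXPA and XTH share members such as EXPA4 and XTH18 with the cell wall list, so they are not separate support for it. The 13 expansin genes of the EXPA family had a median of -0.21 (camera adjusted p = 0.00767; adjusted p = 0.0329 with an estimated correlation) and the 9 XTH genes a median of -0.40 (adjusted p = 0.00396; adjusted p = 0.0296 with an estimated correlation), with 1 and 0 single calls. Against level flight, both were lower at parabola 10 end with the preset correlation (adjusted p = 0.0242 and 0.0197; adjusted p = 0.075 for both with an estimated correlation). They were among 7 families that passed there with the preset correlation, and 0 passed with an estimated one.

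Of the 51 UDP-glycosyltransferase genes of the UGT family, 11 fell at parabola 1 start (median -0.08, adjusted p = 3.52e-04; adjusted p = 0.228 with an estimated correlation) and 10 in tube A (adjusted p = 3.86e-04; adjusted p = 0.146 with an estimated correlation), and 6 were lower in tube A than in tube B (adjusted p = 5.95e-04; adjusted p = 0.269 with an estimated correlation). The family was also lower for the midpoint mean, with 6 genes (adjusted p = 0.00945; adjusted p = 0.445 with an estimated correlation), at parabola 1 end, with 4 (adjusted p = 0.0207; adjusted p = 0.601 with an estimated correlation), and at parabola 3 end, with 2 (adjusted p = 0.0181; adjusted p = 0.875 with an estimated correlation), and did not pass in tube B (adjusted p = 0.443) or at parabola 10 end (adjusted p = 0.374). Of the 10 U-box ubiquitin ligase genes of the PUB family, 3 fell at parabola 1 start (adjusted p = 0.00576; adjusted p = 0.335 with an estimated correlation), 5 in tube A (adjusted p = 2.07e-04; adjusted p = 0.146 with an estimated correlation), none in tube B (adjusted p = 0.0117; adjusted p = 0.273 with an estimated correlation) and 1 at parabola 10 end (adjusted p = 0.00722; adjusted p = 0.113 with an estimated correlation); the family did not pass at parabola 1 end (adjusted p = 0.51) or parabola 3 end (adjusted p = 0.711), where 1 gene each fell. In tube A against tube B, 3 PUB genes were lower (adjusted p = 0.0246; adjusted p = 0.526 with an estimated correlation), and the midpoint mean had 3 lower (adjusted p = 1.31e-04; adjusted p = 0.148 with an estimated correlation).

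Against the mean of the other 6 tubes, limma called 794 probe sets in tube A, 516 at parabola 10 end, 452 in level flight, 300 at parabola 1 start, 94 at parabola 1 end, 41 at parabola 3 end and 4 in tube B. The level flight tube was higher at 328 and lower at 124.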
